A study of Mus musculus with 42 samples.

How the data were processed

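Whole left lungs were collected from 42 mice of a strain prone to lung tumours 70 days after exposure to 56Fe particles, or after no exposure. Per the labels' protocols, the tissue was flash frozen, total RNA was extracted with a column kit, and biotinylated cRNA was hybridised to Illumina BeadChip arrays with 1 array per mouse. The unit of replication was therefore the mouse, and each group was taken from the source label of its samples. The sex of each animal and the slide and position of each array were taken from the labels.

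The authors' non-normalized table holds a mean signal intensity per probe and array on a linear scale, per the file headers, and no normalization. The same deposited table gives a detection p-value per probe and array. The deposited value table holds log2 values, which the authors had normalized so that the sorted columns differed by at most 0.01 between arrays. Its 41 filled columns each had a median of 3.96, and it held values between 1.91 and 15.37. Set against the signals of the same arrays, these columns had a Spearman correlation of at least 0.999997. Their deviations between arrays followed those of the newly normalized log2 values with a slope of 1.06, from which a log2 scale was read. What background step preceded that normalization stays unknown, as does the software, which is not given in the sources used here. The column of fractionated replicate 13 was empty, so the signal of that array in the other table was used (1 empty column).

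The signals were background corrected and normalized in limma 3.58.1 under R 4.3.3 with its function neqc, which fits a normal plus exponential model, adds an offset of 16, and applies quantile normalization and a log2 transformation. Negative control probes were not used here, so the background was inferred from the detection p-values. A probe was tested if its detection p was under 0.01 on at least 13 arrays, the size of the smallest group, which left 17927 probes. Gene names came from the annotation of the array platform, with symbols updated through gene identifiers and accessions in a table of RefSeq genes of assembly GRCm38.p6, which was used only for names, chromosomes and the order of genes. Of the probes 34885 had 1 gene symbol, 18 had several and 10378 were not named, and 34818 matched the current gene table. No gene was named from a probe with several symbols. A gene was represented in the list tests by its tested probe of highest mean, which gave 10296 genes. No coordinates are given.

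Differences were tested with limma on the log2 scale, with group and sex as terms, all 42 arrays in 1 fit, moderated variances with a trend on mean signal, and two-sided p-values adjusted by the Benjamini-Hochberg method over the probes of each comparison. A probe was called at an adjusted p under 0.05. The comparisons were fractionated against control, acute against control, fractionated against acute, an F test over the 3 groups, male against female, and the interaction of sex with each kind of irradiation. Values given as differences are differences of log2 signal with their standard error (SE), and confidence intervals are at 95%. The number of arrays limits the precision: the median interval of a probe reached 0.25 on the log2 scale to either side in each comparison between groups.

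Before the data were examined, 38 gene lists were fixed for the radiation response, lung and immune cell types, oncogene output and tumour markers, metabolism, and tissues or handling effects that a lung sample can carry. They asked for 938 genes, of which 867 had a named probe and 696 were tested. Lists were tested with camera, which compares the shift of a list with that of the other genes, at a preset inter-gene correlation of 0.01 and also with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists of a comparison. A score per mouse and list, the mean deviation of its genes from their average over the arrays, was compared between groups by a two-sided permutation test with 100000 draws, which was added after the data were seen. That test took no account of slide or of sex, although sex is a term in the fit behind camera. Within a slide, group means of these scores and of single genes were compared without fractionated replicate 13. Lists called on the same arrays tend to keep their direction over slides, so slide counts of called lists are no separate evidence.

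The genes named in the text followed a rule written beforehand. They were the 10 largest increases and 10 largest decreases among called probes with 1 symbol, the up to 4 members of smallest p in a called list, the 10 genes of smallest p where fewer than 10 passed, and in every comparison a few fixed genes, including Cdkn1a, Mki67, Sftpc and Scgb1a1. Mki67 was not analysed here, since no probe carried its symbol in the annotation used. Of the members the rule allowed, the text gives the first few by p. Clone and predicted names were not printed.

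The fit was tested on simulated data. In each of 20 simulations per comparison, 200 of the 17927 probes were changed by 0.25, 0.5, 1 or 2 on the log2 scale, with the spread of the real arrays. For fractionated against control 52.8% of the probes changed by 0.5 on the log2 scale and 93.8% of those changed by 1 were recovered, with a median of 1 false call. For acute against control these shares were 54.1% and 93.1%, and for fractionated against acute 56.8% and 94.4%. Of the probes changed by 0.25, only 6.6%, 9% and 10.6% were recovered in these comparisons, so most changes of that size would be missed. All sizes were mixed in each simulation, and the larger changes ease the adjusted threshold for the smaller ones. These shares therefore do not hold for data with small changes alone, which were not simulated. A list shifted by 0.3 was called by camera in 18, 18 and 20 of 20 simulations for these comparisons, with a median of 9, 10.5 and 12 unshifted lists called beside it. With the estimated correlation it was called in 12, 10 and 12, with a median of 0 others.

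The alternatives fixed beforehand were no background correction, an offset of 50, median scaling, the authors' value table, no filter on dim probes, detection on every array, the slide as a fixed or random block, no sex term, fits on the compared groups, on each sex, and without the array that was alone on its slide, array weights, robust moderation, a threshold without adjustment or with a minimum change, the estimated correlation, and split controls. Fits without fractionated replicate 13, with and without the slide as a block or the array lacking Xist, and fits on slides 3 to 5 or on the other slides were added after the data were seen. Scores, tables and figures were made with the R package data.table (version 1.17.8), numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.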

Results

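Expression was profiled in the whole left lung of 42 mice of a strain in which lung tumours arise spontaneously. Of these, 15 mice had received 1.0 Gy of 56Fe particles, heavy nuclei of the kind found in cosmic radiation, in a single exposure (acute, 8 males and 7 females). Another 14 mice had received the same total dose as 5 exposures of 0.2 Gy (fractionated, 7 males and 7 females), and 13 mice were left unirradiated (control, 7 males and 6 females). The design text of the series counts 13 fractionated mice, while 14 arrays carry that label. Of these, fractionated replicate 13 had the 1 empty column of the deposited value table, and whether it is the mouse not counted stays unknown. The particles had an energy of 1.0 GeV per nucleon, and all lungs were taken 70 days after exposure. The design asks which transcripts differ in the lung long after irradiation, and whether dividing the dose changes them.

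Each lung was measured on 1 array, on which 16264 to 18289 probes were detected (median 16974). The median signal of an array lay between 90.5 and 155, and the 95th percentile of the signal between 1088 and 3898. Fractionated replicate 13, a female, stood apart from all other lungs: its correlation with the median profile was 0.931, against 0.983 to 0.996 for the other 41 arrays. In this lung the cell cycle genes lay 3.81 above the median of the other arrays on the log2 scale, and the T and NK cell genes 1.39 above. Its heart and skeletal muscle genes lay at -2.89 and its endothelial genes at -2.02 relative to the same median, and of the 38 lists scored it was above all other arrays in 5 and below them in 18. Since this mouse weighs on several comparisons, the lists called between groups are also given without it, as are genes named there that it moved by more than a factor of 1.5.

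The arrays were spread over 8 slides, of which 7 held all 3 groups and slide 8 held 1 fractionated male. Over the 41 other arrays the second principal component, with 17.7% of the variance, separated slides 3 to 5 (17 arrays) from the rest (24 arrays), and slide accounted for 93.9% of it. Slide explained a median of 34.6% of the variance of a probe over these 41 arrays, group 2.0% and sex 1.97%, over 3000 probes drawn at random. Slide was entered before sex and group, and its 8 levels take up more variance by chance than the groups or the sexes do. The shares are therefore not on the same footing.

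**Figure D1:**
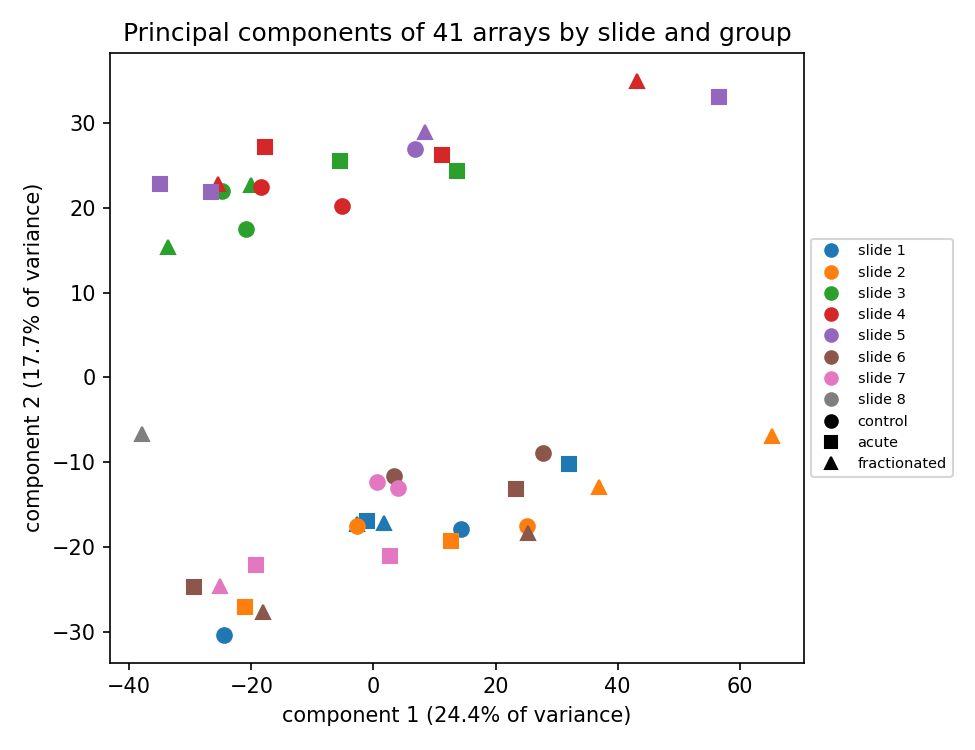
Scores of 41 arrays on the first principal component (x axis, 24.4% of variance) and the second (y axis, 17.7% of variance), with colour for slide and shape for group, fractionated replicate 13 left out. The 17 arrays of slides 3 to 5 lie above 15 on the second component and the other 24 at -6.66 or below, and each set holds all 3 groups.

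Between fractionated and control lungs, the gene of smallest p was Zdhhc17, which encodes a protein palmitoyltransferase, at -0.47 ± 0.11 (log2 difference ± SE, n = 14 and 13, 95% interval -0.70 to -0.25). Its mean log2 signal was 6.44 ± 0.39 (SD) in fractionated and 6.91 ± 0.28 in control lungs. Glud1, the mitochondrial glutamate dehydrogenase, lay at -0.31 ± 0.090, and Ypel3, a growth suppressor that responds to p53, at -0.27 ± 0.076. The receptor phosphatase Ptprk lay at -0.35 ± 0.10 and Herpud2 at -0.34 ± 0.090. On the higher side were Pole4, a subunit of DNA polymerase epsilon, at 0.35 ± 0.10, and Trappc12, a component of a vesicle tethering complex, at 0.35 ± 0.097. The small cap-binding subunit Ncbp2 lay at 0.34 ± 0.095, Fam185a at 0.32 ± 0.086, and the proteasome subunit Psmd1 at 0.26 ± 0.073. None of these 10 genes passed the test over all genes, each having an adjusted p of 0.934. Slide as a block gave -0.48 for Zdhhc17, -0.28 for Glud1, -0.28 for Ypel3, -0.36 for Ptprk and -0.31 for Herpud2. It gave 0.30 for Pole4, 0.35 for Trappc12, 0.29 for Ncbp2, 0.29 for Fam185a and 0.27 for Psmd1. Within slides, Zdhhc17 was lower in fractionated lungs on 7 of 7 (-1.08 to -0.033), as were Ptprk (-0.50 to -0.17), Glud1 (-0.44 to -0.11) and Ypel3 (-0.53 to -0.0097). Trappc12 (0.11 to 0.74) and Ncbp2 (0.093 to 0.43) were higher on 7 of 7. Herpud2 was lower on 6 (-0.76 to 0.14), and Fam185a (-0.026 to 0.36), Psmd1 (-0.079 to 0.50) and Pole4 (-0.020 to 0.64) were higher on 6 of the 7 slides. Genes picked by smallest p on the same arrays tend to keep their direction over slides, so these counts add no support. In this comparison limma called 0 of 17927 probes, with 784 probes at an unadjusted p under 0.05 (376 higher and 408 lower), where 896 would be expected on average by chance. Random splits of the group labels gave a median of 782, and 50 of 100, the real one included, gave as many as 784.

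At the preset correlation of 0.01 camera called 14 of 38 lists between fractionated and control lungs, 3 up and 11 down. Random splits of the group labels called a median of 12 lists. The estimated correlation was higher than the preset, at 0.80 for cell cycle, 0.68 for endothelium, 0.56 for alveolar type 1 cells and 0.17 for oxidative phosphorylation. Without fractionated replicate 13, 8 lists were called, 4 up and 4 down, 5 of them among the 14. With slide as a block besides, 10 were called, 4 up and 6 down, 7 of them among the 14. Genes of oxidative phosphorylation, the respiratory chain of mitochondria, had a median difference of 0.076, with 67 of 77 members higher (camera adjusted p = 9.65e-08, adjusted p = 0.649 with an estimated correlation). The complex I subunits Ndufb2 (0.34 ± 0.13) and Ndufa8 (0.14 ± 0.053) had the smallest p among them. The median was 0.068 with slide as a block and 0.059 without replicate 13 (camera adjusted p = 4.62e-04), and on 5 of 7 slides the score was higher (-0.042 to 0.17). All 24 cell cycle genes were higher, with a median of 0.33 (camera adjusted p = 2.19e-06, adjusted p = 0.668 with an estimated correlation), led by the replicative helicase subunits Mcm6 (0.52 ± 0.27) and Mcm5 (0.41 ± 0.23). Without replicate 13 the cell cycle median was 0.063 (camera adjusted p = 0.203), Mcm6 lay at 0.27 and Mcm5 at 0.18. The cell cycle median was 0.34 with slide as a block, and the score was higher on 4 of 7 slides (-0.55 to 0.62). The 22 genes of DNA repair had a median of 0.061 (camera adjusted p = 0.0480, adjusted p = 0.671 with an estimated correlation). Among them were Brca2 at 0.44 ± 0.17 (0.29 without replicate 13) and the damage recognition factor Xpc at -0.17 ± 0.068. That median was 0.080 with slide as a block, with the score higher on 6 of 7 slides (-0.10 to 0.075), and -0.012 without replicate 13 (camera adjusted p = 0.899).

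Of the lung cell types listed, 4 were called down in the fractionated group, of which 0 passed without the same mouse, and endothelium and alveolar type 1 cells without it and with slide as a block. Endothelial genes had a median of -0.21 (25 of 26 genes lower, camera adjusted p = 1.75e-05, adjusted p = 0.668 with an estimated correlation). Their members included the receptors Flt4 at -0.41 ± 0.20 and Eng at -0.45 ± 0.26 (-0.26 without replicate 13). Genes of alveolar type 1 cells, the thin cells of gas exchange, had a median of -0.17 (16 of 16 lower, camera adjusted p = 2.53e-04, adjusted p = 0.668 with an estimated correlation). Members of smallest p were Gprc5a and the collagen chain Col4a4, both at -0.28, the latter at -0.15 without that mouse. Fibroblast genes had a median of -0.18 (20 of 21 lower, camera adjusted p = 9.69e-04, adjusted p = 0.668 with an estimated correlation). They included Serpinf1 at -0.26 ± 0.11 and Dpep1 at -0.38 ± 0.22, which were -0.17 and -0.23 without it. Genes of alveolar type 2 cells, which make surfactant, had a median of -0.11 (17 of 20 lower, camera adjusted p = 0.00262, adjusted p = 0.671 with an estimated correlation). Among them were the surfactant protein gene Sftpb at -0.41 ± 0.17 and Lamp3 at -0.40 ± 0.21. Without replicate 13 these medians were -0.075 for endothelium (camera adjusted p = 0.0576), -0.069 for alveolar type 1 cells (0.0702), -0.083 for fibroblasts (0.0873) and -0.058 for alveolar type 2 cells (0.0576). The medians with slide as a block were -0.22, -0.19, -0.16 and -0.073, and under median scaling that of alveolar type 2 cells was -0.024 and lost its call (camera adjusted p = 0.238). Other lung cell lists were not called: smooth muscle lay at -0.13 (camera adjusted p = 0.102) and mesothelium at -0.12 (0.103), while 15 of 18 genes of ciliated cells were higher (0.072, 0.183). Each of the 4 scores was higher on 4 and lower on 3 of the 7 slides, with ranges of -0.57 to 0.28 for endothelium, -0.38 to 0.16 for alveolar type 1 cells, -0.46 to 0.24 for fibroblasts and -0.61 to 0.31 for alveolar type 2 cells.

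The remaining lists called in this comparison covered blood, other tissues and signalling. Red blood cell genes had a median of -0.37 (8 of 9 lower, camera adjusted p = 9.69e-04, adjusted p = 0.649 with an estimated correlation). Their members included the haem synthesis enzymes Alas2 at -0.88 ± 0.35 and Fech at -0.44 ± 0.25. B and plasma cell genes had a median of -0.16 (13 of 14 lower, camera adjusted p = 0.00728, adjusted p = 0.668 with an estimated correlation). Members of smallest p were the kinase Blk at -0.53 ± 0.24 and the receptor chain Cd79b at -0.39 ± 0.18. Heart and skeletal muscle genes had a median of -0.37 (22 of 24 lower, camera adjusted p = 0.00231, adjusted p = 0.671 with an estimated correlation). They included sarcolipin, Sln, at -0.95 ± 0.65 and cardiac actin, Actc1, at -0.58 ± 0.41, which were -0.60 and -0.27 without replicate 13. Adipose genes had a median of -0.56 (6 of 8 lower, camera adjusted p = 0.0259, adjusted p = 0.668 with an estimated correlation). Among them were carbonic anhydrase Car3 at -1.52 ± 0.79 and Thrsp at -0.70 ± 0.38, while in males alone the list lay at 0.054 and Thrsp at 0.037. Immediate early genes had a median of -0.19 (15 of 17 lower, camera adjusted p = 3.89e-04, adjusted p = 0.649 with an estimated correlation). Their members included Nr4a2 at -0.37 ± 0.18 and the phosphatase Dusp1 at -0.29 ± 0.18 (-0.13 without replicate 13). Circadian clock genes had a median of -0.16 (9 of 11 lower, camera adjusted p = 0.0119, adjusted p = 0.649 with an estimated correlation). Members of smallest p were Cry2 at -0.28 ± 0.11 and Tef at -0.33 ± 0.20. Genes of Ras and MAPK output had a median of -0.11 (13 of 15 lower, camera adjusted p = 0.0300, adjusted p = 0.668 with an estimated correlation). They included Dusp6 at -0.11 ± 0.078 and Spred1 at -0.17 ± 0.12, or -0.071 and -0.087 without replicate 13.

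Without fractionated replicate 13 the calls for adipose tissue (median -0.40, camera adjusted p = 0.109), the circadian clock (-0.075, 0.0702) and Ras and MAPK output (-0.071, 0.109) were lost. Those for red blood cells (-0.28, 0.0165), B and plasma cells (-0.14, 0.0267), muscle (-0.21, 0.0311) and immediate early genes (-0.088, 0.0267) passed again. With slide as a block besides, immediate early genes did not pass (-0.065, camera adjusted p = 0.0707). Oxidative phosphorylation (0.052, 0.00140), red blood cells (-0.34, 0.0198), B and plasma cells (-0.15, 0.0279), muscle (-0.27, 0.0105), endothelium (-0.079, 0.0480), alveolar type 1 cells (-0.079, 0.0480) and the clock (-0.095, 0.0480) did, 7 of the 10 lists called there. In all lungs, with slide as a block the medians were -0.43 for red blood cells, -0.12 for B and plasma cells, -0.53 for muscle and -0.67 for adipose tissue. They were -0.18 for immediate early genes, -0.21 for the circadian clock and -0.087 for Ras and MAPK output, the last no longer called (camera adjusted p = 0.0998). Within slides, red blood cell genes were lower on 6 of 7 (-0.94 to 0.037). Adipose (-1.53 to 0.23), immediate early (-0.46 to 0.27) and clock genes (-0.64 to 0.059) were lower on 5, B and plasma cell (-0.88 to 0.72) and muscle genes (-1.12 to 0.20) on 4, and Ras and MAPK genes (-0.36 to 0.18) on 3. On slides 3 to 5 alone the direction turned for muscle (0.10), Ras and MAPK output (0.090) and, by the test, fibroblasts (-0.0054), and none of the 3 was called there. The other 24 lists did not pass in all lungs, among them p53 targets (median 0.027, camera adjusted p = 0.459), senescence genes (0.11, 0.435), cytokines (0.073, 0.106) and extracellular matrix genes (-0.091, 0.0620). Without replicate 13, 8 lists were called, among them ciliated cells (0.20, camera adjusted p = 2.06e-04), the interferon response (0.12, 0.0267) and cytokines (0.15, 0.0445), none of the 3 called in all lungs. No list passed with an estimated correlation or by permutation of the scores per mouse (smallest p 0.103, adjusted p 0.708). No member of any list passed, whether adjusted over all genes or adjusted over the list alone (count 0 by limma in either case, with 784 probes of all 17927 at an unadjusted p under 0.05). Under median scaling 16 lists were called, 6 up and 10 down, without Ras and MAPK output (-0.071, camera adjusted p = 0.0732), and 7 lists, 3 up and 4 down, in the authors' value table, which lacks replicate 13.

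Between acute and control lungs the smallest p belonged to Araf, a kinase of the Raf family that acts downstream of Ras, at 0.21 ± 0.056 (n = 15 and 13, 95% interval 0.10 to 0.33), with mean log2 signals of 10.60 ± 0.14 (SD) and 10.38 ± 0.089. The interferon-inducible Ifi27 lay at 0.20 ± 0.067, the apoptosis repressor Nol3 at 0.37 ± 0.13, Spats2l at 0.32 ± 0.098 and the ribosomal RNA processing factor Rrp36 at 0.26 ± 0.083. On the lower side were the aminopeptidase Xpnpep1 at -0.36 ± 0.10, the hydroxylase Asph at -0.33 ± 0.10, and Glud1 at -0.28 ± 0.088. The mitochondrial carrier Slc25a11 lay at -0.25 ± 0.085 and Egln1, the oxygen-sensing prolyl hydroxylase, at -0.22 ± 0.072. None of the 10 passed the test over all genes, with adjusted p-values of 1.00. In the fit with slide as a block Araf lay at 0.21, Ifi27 at 0.20, Nol3 at 0.35, Spats2l at 0.32 and Rrp36 at 0.23. Xpnpep1 lay at -0.35, Asph at -0.31, Glud1 at -0.26, Slc25a11 at -0.23 and Egln1 at -0.20. Within slides Araf (0.070 to 0.37), Ifi27 (0.055 to 0.41) and Rrp36 (0.033 to 0.57) were higher on 7 of 7, and Xpnpep1 (-0.50 to -0.13), Asph (-0.56 to -0.067) and Glud1 (-0.45 to -0.099) lower on 7 of 7. The others had the same direction on 6 of the 7 slides, with ranges of -0.023 to 0.64 for Nol3, -0.14 to 0.67 for Spats2l, -0.49 to 0.12 for Slc25a11 and -0.53 to 0.035 for Egln1. Here too the choice by smallest p on the same arrays favours a shared direction, so the slide counts add no support. By limma 0 probes were called and 253 had an unadjusted p under 0.05 (141 higher and 112 lower), against 896 expected on average by chance. The count was not unusual for these samples, since random splits gave a median of 295 and 56 of 100, the real one included, gave as many as 253.

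In acute lungs 4 of 38 lists were called by camera, 1 up and 3 down, where random splits of the group labels called a median of 8. Interferon response genes had a median of 0.13 (16 of 18 higher, camera adjusted p = 2.28e-04, adjusted p = 0.619 with an estimated correlation). Among them were the antiviral genes Oasl2 at 0.36 ± 0.18 and Mx2 at 0.38 ± 0.21. Adipose genes had a median of -0.40 (7 of 8 lower, camera adjusted p = 0.00312, adjusted p = 0.619 with an estimated correlation). Their members included the lipid droplet protein gene Cidec at -0.56 ± 0.33 and Car3 at -1.16 ± 0.77. Glucocorticoid targets had a median of -0.094 (12 of 15 lower, camera adjusted p = 0.00995, adjusted p = 0.619 with an estimated correlation). Members of smallest p were Pdk4 at -0.41 ± 0.25 and Tsc22d3 at -0.21 ± 0.14. Under median scaling, where the median of all probes was 0.11, that of the list was 0.041 and it was called down again (camera adjusted p = 9.16e-04). Mast cell genes had a median of -0.21 (4 of 5 lower, camera adjusted p = 0.0429, adjusted p = 0.619 with an estimated correlation). They included the proteases Cma1 at -0.38 ± 0.22 and Cpa3 at -0.45 ± 0.29. In males alone the mast cell median had the opposite sign, 0.085, with Cma1 at 0.085 and Cpa3 at 0.42, and under median scaling the median was -0.088. With slide as a block the medians were 0.15, -0.31, -0.11 and -0.19, the mast cell call being lost (camera adjusted p = 0.0551). Within slides interferon genes were higher on 4 of 7 (-0.14 to 0.36), adipose genes lower on 5 (-2.10 to 0.95), glucocorticoid targets lower on 5 (-0.93 to 0.34) and mast cell genes lower on 4 (-0.48 to 0.23). Among the 34 lists that were not called were p53 targets (median 0.071, camera adjusted p = 0.0819), DNA repair (0.033, 0.716), cell cycle (0.051, 0.800), senescence (0.016, 0.940) and lung tumour markers (0.020, 0.743). No list passed by permutation of the scores per mouse (smallest p 0.0931, adjusted p 0.907). By limma 0 members passed over all genes or adjusted over the list alone, with 253 of all probes at an unadjusted p under 0.05. Leaving out fractionated replicate 13, which enters this comparison only through the shared fit, gave 8 called lists, 2 up and 6 down. With slide as a block besides, 5 were called, 3 of them among the 4, and mast cells were not (-0.19, camera adjusted p = 0.110). Under median scaling 13 lists were called, 3 up and 10 down, with a median difference of 0.11 over all probes, and 4 lists, 2 up and 2 down, in the value table.

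Set directly against each other, fractionated and acute lungs differed most clearly, though without passing the test, in Me2, the mitochondrial malic enzyme, at 0.30 ± 0.076 (n = 14 and 15, 95% interval 0.14 to 0.45), with mean log2 signals of 8.03 ± 0.24 (SD) and 7.74 ± 0.16. Higher in fractionated lungs were also the ubiquitin ligase Fbxo32 at 0.38 ± 0.11, the annexin Anxa8 at 0.60 ± 0.19 and the phosphatase subunit Ppp2r5e at 0.23 ± 0.075. Lower were the lipid transporter Abca4 at -0.43 ± 0.11, the phosphodiesterase Pde4b at -0.40 ± 0.12 and the immune receptor Pilra at -0.33 ± 0.11. The p38 family kinase Mapk12 lay at -0.30 ± 0.094, Ypel3 at -0.28 ± 0.074 and the Ras effector Rgl2 at -0.28 ± 0.085. The adjusted p of each was 1.00. Blocking on slide gave 0.29 for Me2, 0.39 for Fbxo32, 0.63 for Anxa8 and 0.17 for Ppp2r5e. It gave -0.44 for Abca4, -0.37 for Pde4b, -0.33 for Pilra, -0.31 for Mapk12, -0.27 for Ypel3 and -0.24 for Rgl2. Me2 was higher on 7 of 7 slides (0.086 to 0.34), and Abca4 (-0.79 to -0.20), Mapk12 (-0.39 to -0.011) and Rgl2 (-0.34 to -0.11) were lower on 7 of 7. Fbxo32 (-0.058 to 0.78), Ppp2r5e (-0.015 to 0.33), Ypel3 (-0.43 to 0.016) and Pilra (-0.76 to 0.040) had the direction of the pooled value on 6 slides, and Anxa8 (-0.073 to 1.17) and Pde4b (-0.84 to 0.17) on 5. Since these genes were also picked by smallest p on the same arrays, their slide counts add no support. By limma 0 probes were called, with 372 at an unadjusted p under 0.05 (171 higher and 201 lower), where random splits gave a median of 725.

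Of the 38 lists 8 were called between fractionated and acute lungs, 3 up and 5 down, where random splits of the group labels called a median of 13. Oxidative phosphorylation genes had a median of 0.064 (67 of 77 higher, camera adjusted p = 7.81e-10, adjusted p = 0.825 with an estimated correlation). Among them were the ATP synthase subunit Atp5e at 0.25 ± 0.11 and Ndufv2 at 0.10 ± 0.046. Under median scaling that median was -0.0057, against -0.097 for all probes, and the list was called up again (camera adjusted p = 7.19e-07). All 24 cell cycle genes were higher, with a median of 0.28 (camera adjusted p = 4.78e-08, adjusted p = 0.835 with an estimated correlation) and with the replication factor Cdc6 at 0.40 ± 0.25 (0.16 without replicate 13). All 17 immediate early genes were lower, with a median of -0.21 (camera adjusted p = 2.93e-05, adjusted p = 0.835 with an estimated correlation). Their members included Nr4a2 at -0.36 ± 0.17 and Jund at -0.30 ± 0.15. Cholesterol and fatty acid synthesis genes had a median of 0.11 (14 of 19 higher, camera adjusted p = 0.00485, adjusted p = 0.835 with an estimated correlation). Members of smallest p were Sqle, an enzyme of sterol synthesis, at 0.28 ± 0.11 and Nsdhl at 0.23 ± 0.14. Under median scaling, where the median of all probes was -0.097, that of the list was 0.00041, although still called up (camera adjusted p = 4.14e-04). Another 4 lists were called, among them endothelium (median -0.16, camera adjusted p = 0.00177, with Egfl7 at -0.31 ± 0.15) and alveolar type 1 cells (-0.12, 0.00485, with Gprc5a at -0.23 ± 0.12 and the water channel Aqp5 at -0.18 ± 0.11). Besides these there were the circadian clock (-0.15, 0.0314, with Dbp at -0.48 ± 0.30) and alveolar type 2 cells (-0.11, 0.0371, with Sftpb at -0.26 ± 0.16 and the lipid transporter Abca3 at -0.14 ± 0.088). These had an adjusted p = 0.835 with an estimated correlation. On slides 3 to 5 alone alveolar type 1 cells were called in the opposite direction (0.11, camera adjusted p = 0.0438), and endothelium (0.13), cholesterol synthesis (0.0011 with the test pointing down) and the clock (-0.0068 with the test pointing up) turned without a call. Endothelium lay at 0.0081 with array weights, and alveolar type 2 cells at 0.042 in males alone. Without fractionated replicate 13, 3 of the 8 calls remained, namely oxidative phosphorylation (0.042, camera adjusted p = 7.43e-05), immediate early genes (-0.13, 0.00921) and cholesterol synthesis (0.10, 0.00921). The others were at 0.018 for cell cycle, 0.0042 for endothelium, -0.012 for alveolar type 1 cells, -0.095 for the circadian clock and -0.049 for alveolar type 2 cells, with Gprc5a at -0.14, Aqp5 at -0.095 and Abca3 at -0.074. When slide was a block besides, immediate early genes did not pass (-0.075, camera adjusted p = 0.107), which left oxidative phosphorylation (0.025, 0.00609) and cholesterol synthesis (0.12, 0.00609) of the 8, with alveolar type 2 cells at 0.00024.

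The 8 medians with slide as a block were 0.052 for oxidative phosphorylation, 0.32 for cell cycle, -0.15 for immediate early genes, 0.14 for cholesterol synthesis, -0.18 for endothelium, -0.16 for alveolar type 1 cells, -0.19 for the circadian clock and -0.046 for alveolar type 2 cells, the last no longer called (camera adjusted p = 0.392). Within slides oxidative phosphorylation (-0.096 to 0.089) and cholesterol synthesis (-0.12 to 0.47) were higher in fractionated than in acute lungs on 5 of 7, and cell cycle (-0.48 to 0.64) on 4. Immediate early (-0.57 to 0.26), alveolar type 1 (-0.45 to 0.29) and clock genes (-0.47 to 0.16) were lower on 5, alveolar type 2 genes (-0.46 to 0.48) on 4 and endothelial genes (-0.63 to 0.33) on 3. No list passed by permutation of the scores per mouse (smallest p 0.101, adjusted p 0.911), and by limma 0 members passed over all genes or adjusted over the list alone, with 372 probes of all those tested at an unadjusted p under 0.05. Under median scaling 11 lists were called, 8 up and 3 down, without the circadian clock (-0.24, camera adjusted p = 0.0602) and alveolar type 2 cells (-0.15, 0.476), and 3 lists, 2 up and 1 down, in the value table.

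**Figure D2:**
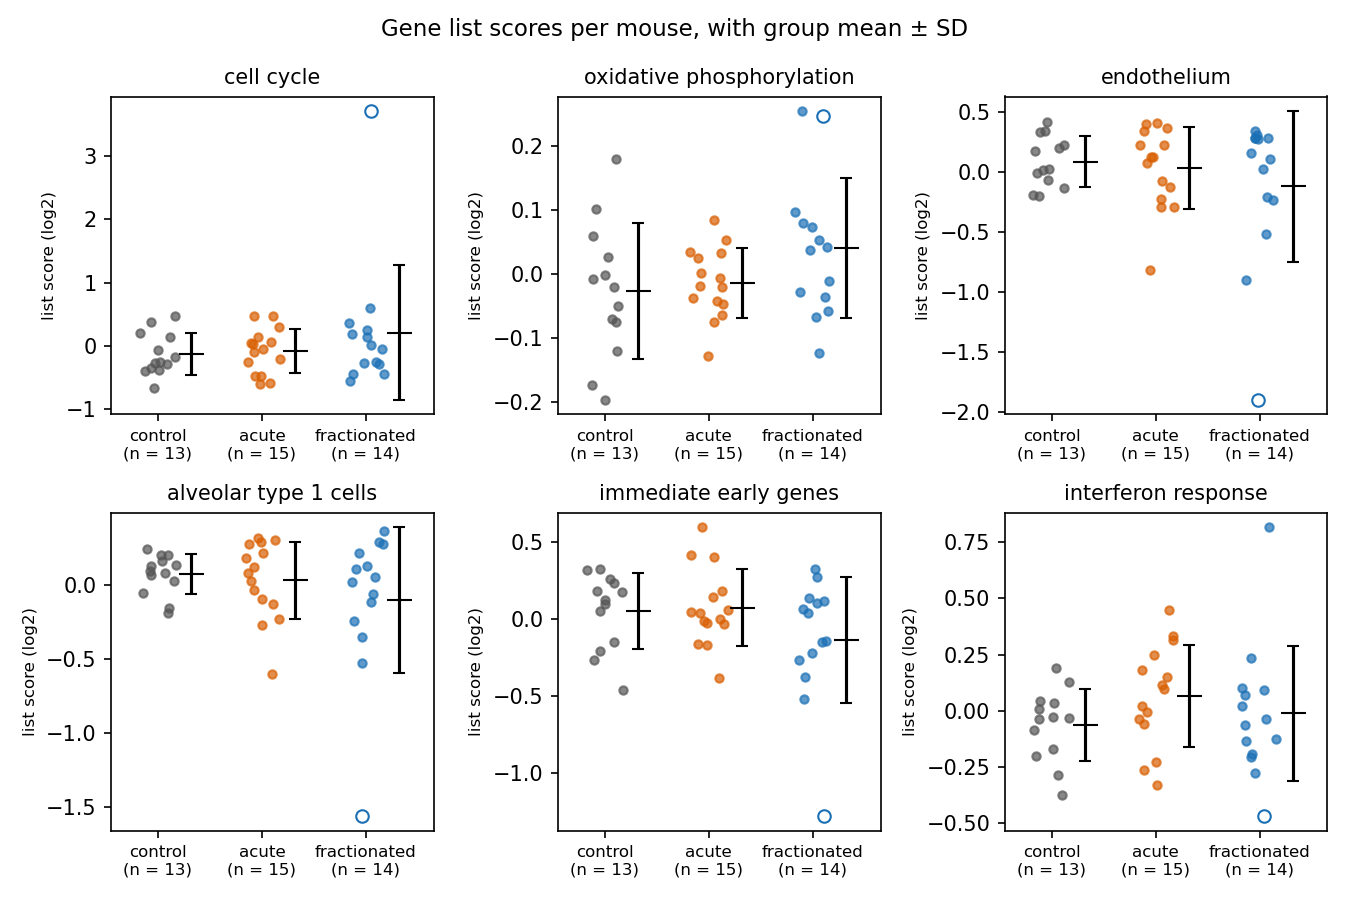
Score of 6 gene lists in each mouse (y axis, mean log2 deviation of the list's genes from their average over the arrays) by group (x axis), with 1 point per mouse and the group mean ± SD as bars, the open circle being fractionated replicate 13. The groups overlap in each panel, and the open circle lies at 3.72 for cell cycle genes, at -1.89 for endothelium and at -1.56 for alveolar type 1 cells, outside the range of the other 41 mice in each of the 3.

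None of the genes fixed for every comparison passed. Cdkn1a, the p53-induced inhibitor of the cell cycle, lay at 0.14 ± 0.21 in fractionated and 0.13 ± 0.21 in acute lungs relative to control, with intervals of -0.29 to 0.57 and -0.29 to 0.55. Sftpc, the surfactant gene of alveolar type 2 cells, lay at -0.085 ± 0.072 and -0.068 ± 0.071, and Scgb1a1, the secretory protein of club cells, at 0.012 ± 0.071 and 0.022 ± 0.070. Between fractionated and acute lungs the values were 0.014 ± 0.21, -0.016 ± 0.069 and -0.0099 ± 0.069. Without replicate 13 these 3 were 0.072, 0.00016 and -0.022, and Scgb1a1 lay at -0.00061 for fractionated against control. With slide as a block besides, Cdkn1a lay at 0.30 and Scgb1a1 at -0.040 for fractionated against control, and for fractionated against acute Cdkn1a lay at 0.19, Sftpc at -0.0096 and Scgb1a1 at -0.073. When slide was a block for all lungs, Cdkn1a lay at 0.22 and Sftpc at -0.073 for fractionated against control, where Scgb1a1 changed sign to -0.018. On the 7 slides Cdkn1a was higher in fractionated than in control lungs on 4 (-0.55 to 1.44), and Sftpc (-0.28 to 0.037) and Scgb1a1 (-0.17 to 0.36) were lower on 5.

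An F test over the 3 groups in limma called 0 probes, with 370 at an unadjusted p under 0.05. To ask whether acute and fractionated exposure moved genes together, the differences of 10296 genes against control were compared. They had a correlation of 0.60 over genes, which are not independent replicates, and 68.9% had the same sign, but both use the same control mice. Simulated groups without any change, compared in the same way, gave a correlation of 0.54 and 68.2% of the same sign. The covariance was 0.00939, against 0.0131 simulated (0.00198 to 0.0296), a difference of -0.00369, and it was 0.00847 without fractionated replicate 13. With the controls split so that each arm had its own, the covariance was -0.000647 and the correlation -0.0041.

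Males and females differed in 318 probes by limma, 219 higher and 99 lower in males (n = 22 and 20, 3016 at an unadjusted p under 0.05), and these lay on autosomes as well as on the sex chromosomes. The Y-linked genes Eif2s3y (4.197 ± 0.11, adjusted p = 1.51e-30) and Kdm5d (1.35 ± 0.091, adjusted p = 6.70e-15) were higher in males, by at least these amounts, since their probes were detected in 1 and 0 of 20 females. Xist, the RNA that silences an X chromosome in females, lay at -5.54 ± 0.28 (adjusted p = 5.45e-19), a lower bound on the size of the difference because its probe was detected in 0 of 22 males, and the X-linked gene Kdm6a (-0.72 ± 0.072), which escapes that silencing, was lower in males. Acute replicate 14, labelled female, had Xist at 4.496, within the male range of 4.36 to 4.97, while the 19 other females lay between 9.67 and 11.47. Autosomal genes higher in males included Hamp, the iron hormone hepcidin, at 1.99 ± 0.38 (adjusted p = 0.00177), the platelet chemokine gene Ppbp at 1.44 ± 0.29, the carboxylesterase Ces1f at 1.45 ± 0.27, and the muscle ankyrin repeat gene Ankrd1 at 1.44 ± 0.25. The phospholipase Pla1a lay at 1.39 ± 0.13, and 3 muscle genes at the edge of the threshold were the myosin light chain Myl1 at 1.64 ± 0.45 (adjusted p = 0.0418), myoglobin, Mb, at 1.59 ± 0.43 (0.0404) and the creatine kinase Ckmt2 at 1.59 ± 0.44 (0.0492). Lower in males were Zmat4 at -1.14 ± 0.26, the oestrogen-responsive Greb1 at -1.01 ± 0.18, and the cadherin Cdh16 at -0.90 ± 0.16, as well as the histone genes H2ac7 at -0.95 ± 0.26 and H2ac12 at -0.95 ± 0.26. Rasl11a lay at -0.85 ± 0.15, the X-linked RNA sensor Tlr8 at -0.81 ± 0.15 and Gpr171 at -0.75 ± 0.16, the probes of Zmat4 and Tlr8 being detected in 6 and 9 of 22 males. The adjusted p-values of the autosomal genes and Tlr8 ran up to 0.0492. Without fractionated replicate 13 the 3 muscle genes did not pass (Myl1 1.58, adjusted p = 0.0503; Mb 1.48, 0.0513; Ckmt2 1.47, 0.0617), and with slide as a block the histone genes did not (H2ac7 -0.88, 0.0628; H2ac12 -0.89, 0.0606).

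On each of 7 slides with both sexes these 20 genes had the direction of the pooled value, except Myl1, Greb1, H2ac7, H2ac12 and Cdh16, which did so on 6. All 20 were chosen from the same arrays, so these slide counts are no separate evidence. Their values with slide as a block ranged from 4.14 for Eif2s3y, 1.88 for Hamp and 1.39 for Ces1f to -1.16 for Zmat4 and -5.56 for Xist. Of the called probes with a gene name, 16 genes lay on the X chromosome (6 higher and 10 lower in males), 3 on the Y chromosome and 219 on autosomes (155 higher and 64 lower). The count was 538 with slide as a block (349 higher and 189 lower) and 400 without fractionated replicate 13 (234 higher and 166 lower), of which 300 and 293 were among the 318. From the authors' values it was 399, with 232 higher and 167 lower, and array weights gave 1165. It was 76 under median scaling (54 higher and 22 lower), all among the 318, and was 186 without the filter, 197 with detection on every array, 225 without the array alone on its slide, 148 on slides 3 to 5 and 35 on the other slides.

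**Figure D3:**
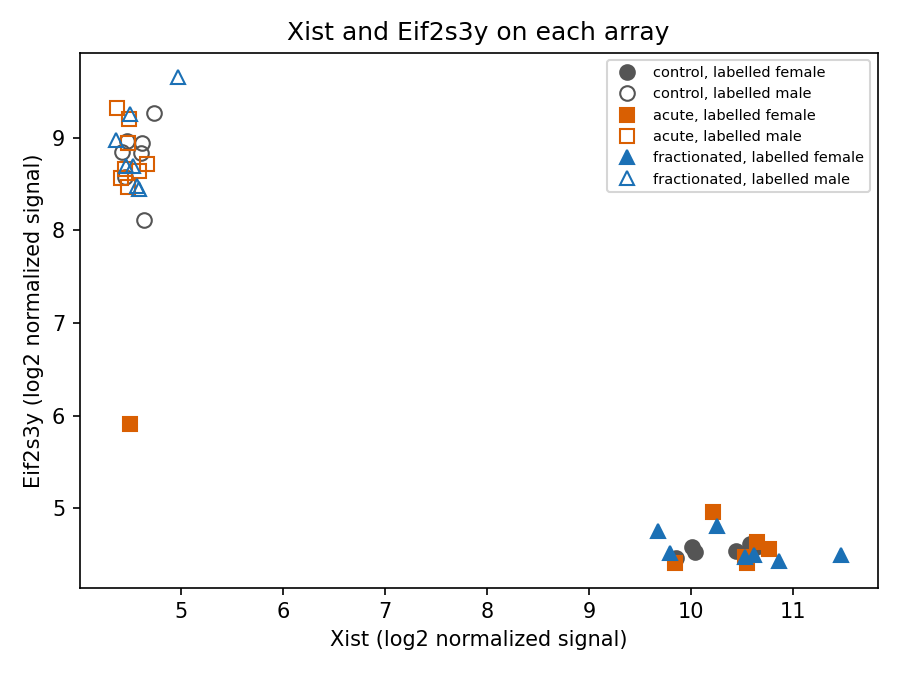
Log2 normalized signal of Xist (x axis) against that of the Y-linked gene Eif2s3y (y axis) on each of 42 arrays, with shape and colour for group, filled symbols for animals labelled female and open symbols for males. The 22 males lie at Xist values up to 4.97 and 19 females at 9.67 or more, while the filled square at 4.496 and 5.91 is acute replicate 14.

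By sex 19 of 38 lists were called by camera, 10 up and 9 down in males, and only the sex-linked list held with the correlation estimated (median 0.93, adjusted p = 9.61e-05 with an estimated correlation). Random splits of the sex labels within groups called a median of 12 lists. Heart and skeletal muscle genes had a median of 1.00 (camera adjusted p = 1.48e-10, adjusted p = 0.228 with an estimated correlation), and 2 of 24 members rose in males over all genes and 20 adjusted over the list alone, among them Mybpc3, a sarcomere protein, at 0.94 ± 0.25. Cell cycle genes had a median of -0.51 (camera adjusted p = 5.24e-10, adjusted p = 0.381 with an estimated correlation), with 0 of 24 called over all genes by limma and 10 adjusted over the list alone, and Prc1 at -0.67 ± 0.20. Without fractionated replicate 13 that median was -0.32 and that of muscle 0.87. Alveolar type 1 genes had a median of 0.30 (camera adjusted p = 7.38e-08, adjusted p = 0.233 with an estimated correlation), and Pdpn (0.29 ± 0.067) and Igfbp2 (0.70 ± 0.17) rose in males, 2 of 16 over all genes and 10 adjusted over the list alone. Genes of MHC class II presentation had a median of -0.34 (camera adjusted p = 3.15e-07, adjusted p = 0.210 with an estimated correlation), with H2-Eb1 at -0.40 ± 0.11 the 1 member called over all genes and 8 of 11 adjusted over the list alone. Mesothelial genes had a median of 0.36 (camera adjusted p = 3.58e-07, adjusted p = 0.176 with an estimated correlation), with Gpm6a (0.57 ± 0.15) and Upk1b (0.46 ± 0.12) called over all genes and 9 of 10 adjusted over the list alone. Nrf2 targets, the oxidative stress genes, had a median of 0.12 (camera adjusted p = 1.95e-06, adjusted p = 0.176 with an estimated correlation), with 4 of 23 called, among them Srxn1 (0.49 ± 0.066) and the quinone reductase Nqo1 (0.87 ± 0.14), and 8 adjusted over the list alone.

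Another 12 lists were called by sex, among them endothelium (median 0.22), club cells (0.27), red blood cells (0.30), ciliated cells (0.22) and oxidative phosphorylation (0.034), higher in males. Those lower in males were ribosomal proteins (-0.061), heat shock genes (-0.13), T and NK cells (-0.20), alveolar type 2 cells (-0.19), macrophages (-0.26), cytokines (-0.20) and DNA repair (-0.063). Their camera adjusted p was 3.42e-05 to 0.0402, and adjusted p = 0.208 or more with an estimated correlation. With slide as a block club cells (0.24, camera adjusted p = 0.0552), red blood cells (0.27, 0.0552) and ciliated cells (0.18, 0.152) were no longer called, and without fractionated replicate 13 these 3 (0.18, 0.26 and 0.098) and DNA repair (-0.0017, 0.233) were not. Without that mouse endothelium lay at 0.14 and ribosomal proteins at -0.040, both still called. Leaving out only the array alone on its slide gave 17 lists called by sex, 8 up and 9 down. Within slides the scores of muscle (0.054 to 1.43), alveolar type 1 cells (0.040 to 0.47), mesothelium (0.064 to 0.88) and Nrf2 targets (0.081 to 0.33) were higher in males on 7 of 7, and those of MHC class II (-0.77 to 0.0091) and cell cycle (-0.73 to 0.16) lower on 6. Of the 12 lists, oxidative phosphorylation was higher on 7 slides, and ribosomal proteins, heat shock genes, T and NK cells and cytokines were lower on 7. Endothelium was higher, and alveolar type 2 cells and macrophages lower, on 6. Red blood cells (-0.62 to 0.93) and ciliated cells (-0.59 to 0.61) were higher on 5. DNA repair was lower on 5 (-0.10 to 0.035) and club cells higher on 4 (-0.49 to 0.74). All these lists were called on the same arrays, so their slide counts are no separate evidence.

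No difference in the response of males and females passed the test. For the interaction of sex with fractionated exposure limma called 0 probes, with 460 at an unadjusted p under 0.05, and for acute exposure 0, with 370. The smallest p among named genes included Cpa3, a mast cell protease, with an interaction of 1.87 for acute exposure (adjusted p = 1.00), and the heat shock protein gene Hspa2 with 0.92 for fractionated exposure (adjusted p = 1.00).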

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

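The settings without fractionated replicate 13, those on part of the slides, and the permutation of list scores were chosen only after the data were seen. The other alternatives were planned. In each comparison between groups limma called 0 probes under 22 settings, with 350 to 2123 at an unadjusted p under 0.05 for fractionated against control, 166 to 1320 for acute against control and 236 to 1657 for fractionated against acute. The smallest adjusted p over these settings was 0.203, 0.181 and 0.222. At an unadjusted p under 0.05 the counts were 784, 253 and 372. Of 270 counts under alternatives, 208 stayed within 1.5 times the reported count or at 0. Of 804 list results 559 kept direction and side of the threshold, 233 lost the call and 12 reversed, and of 2783 results for named genes these numbers were 2603, 104 and 36, with 40 passing where they had not. Called lists ranged from 5 to 20, from 2 to 17 and from 3 to 18 over 19 settings for these comparisons, and from 15 to 21 over 15 settings for sex. For the changes below the cause was not tested, except that fits on fewer probes or mice have fewer values to call.

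Under median scaling acute against control had 13 lists and sex 76 probes. There Sftpc was at 0.0021 in fractionated and 0.050 in acute lungs against control, and Cdkn1a at -0.060 for fractionated against acute. That scaling moved the median of all probes by 0.11 for acute against control, beside which these values are read. From the value table, 7 lists were called for fractionated against control and 3 for fractionated against acute, with Scgb1a1 at 0 in the former and Sftpc at 0.0013 in the latter. Without the filter acute against control had 2 lists and sex 186 probes, and with detection on every array 2 lists and 197 probes. Sex gave 538 probes with slide as a fixed block and 680 with slide as a random block, and Scgb1a1 lay at -0.018 for fractionated against control with the fixed block and also without the array alone on its slide. Array weights gave 9 lists for acute against control and 1165 probes for sex, with endothelium at 0.0081 for fractionated against acute and Scgb1a1 at -0.017 for fractionated against control.

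In males only, 9 lists were called for fractionated and 7 for acute against control. Among males adipose tissue was at 0.054 and Thrsp at 0.037 in fractionated lungs, and mast cell genes at 0.085, Cma1 at 0.085, Cpa3 at 0.42 and Cdkn1a at -0.16 in acute lungs, each against control. For fractionated against acute males had alveolar type 2 genes at 0.042, Sftpc at 0.049 and Scgb1a1 at 0.041. In females only, 14 lists were called for acute against control and 18 for fractionated against acute, with Scgb1a1 at -0.054 for fractionated against control and Cdkn1a at -0.39 for fractionated against acute.

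Without fractionated replicate 13 the lists numbered 8, 8 and 3 for fractionated against control, acute against control and fractionated against acute, with Scgb1a1 at -0.00061 in the first and Sftpc at 0.00016 in the last. With slide as a fixed block besides, fractionated against acute had 3 lists and sex 868 probes, with alveolar type 2 genes at 0.00024 and, against control, Scgb1a1 at -0.040. Without acute replicate 14, which lacked Xist, as well, 8 lists were called for fractionated against control and 5 for fractionated against acute, with Scgb1a1 at -0.00061 and Sftpc at 0.0030.

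On slides 3 to 5 alone, 5 lists were called for fractionated and 10 for acute against control, and 148 probes for sex. For fractionated against control these slides had muscle at 0.10, Ras and MAPK output at 0.090 and fibroblasts at -0.0054 with the test pointing up, and Gprc5a at 0.061, Actc1 at 0.062, Flt4 at 0.17, Spred1 at 0.022 and Cdkn1a at -0.094. Cdkn1a was at -0.051 for acute against control. For fractionated against acute they had alveolar type 1 genes at 0.11, called in that direction (camera adjusted p = 0.0438), endothelium at 0.13, cholesterol synthesis at 0.0011 with the test pointing down, and the circadian clock at -0.0068 with the test pointing up. Among genes Gprc5a was at 0.14, Aqp5 at 0.013, Dbp at 0.035, Nr1d1 at 0.24, Robo4 at 0.097, Sftpc at 0.075 and Cdkn1a at -0.043. On slides 1, 2, 6, 7 and 8 alone 17 lists were called for acute against control, 18 for fractionated against acute and 35 probes for sex, with Scgb1a1 at -0.0022 for fractionated and Sftpc at 0.035 for acute against control.

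With the estimated correlation 0, 0 and 0 lists passed between groups and 1 by sex, and by permutation of the scores per mouse 0, 0 and 0. With the controls split the covariance of the 2 responses was -0.000647. Camera takes neither slide as a random block nor robust moderation, so the lists were not run under these, and the F test was not run on the compared groups alone. No paired analysis was possible because the replicate numbers follow the order of the samples and pair none. For arrays the signal over background limits what can be seen: probes near the background were left out by the filter, and a change in them was not analysed here.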

Other observations

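The tests of failed hybridisation, immature T cells, radiation and a male label below, and all random splits of the samples, were chosen only after the result was seen. Of the net scores of the 38 lists, taken over males and females together, those of muscle, fat and neutrophils varied most. A net score hides members that move apart, as in the sex-linked list (SD 0.24). Over 41 mice, fractionated replicate 13 left out, the score had the largest SD for heart and skeletal muscle (SD 1.00, from -2.06 to 1.908), adipose tissue (SD 0.88) and neutrophils (SD 0.71), on the log2 scale. Club cells (SD 0.56), red blood cells (SD 0.53), cytokines (SD 0.48) and lung tumour markers (SD 0.45) followed. Genes of p53 targets (SD 0.093), the epithelial to mesenchymal transition (SD 0.089), oxidative phosphorylation (SD 0.087), DNA repair (SD 0.071) and ribosomal proteins (SD 0.060) varied least.

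In fractionated replicate 13 genes that developing T cells use to assemble their receptors were far above the other lungs. The recombinase gene Rag1 lay at least 6.42 and Dntt, which adds nucleotides at the joints, at least 7.14 above the median of the other arrays, on none of which their probes were detected. The T cell transcription factor Bcl11b lay 5.97, the signalling adaptor Lat 5.62 and the dividing cells' topoisomerase Top2a 5.83 above it. Arpp21 had 9 probes, detected on none of the others, and lay at least 7.43 above at its probe of largest difference. Its probes at -0.038 and at 0.71, the latter that of highest mean, were not detected on this array either and so measure no difference. These genes were chosen after their values were seen, Bcl11b, Lat and Top2a at the probe of largest difference.

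For this array 16535 probes were detected, inside the range of the other arrays, and its 95th percentile of 2096 was too, which argues against failed hybridisation. Immature T cells in that lung stay open: their 7 genes had a median 0.782 above the other arrays at probes of highest mean, of which those of Rag2, Arpp21 and Themis were detected on no array. A median of 5.08 at probes detected somewhere, chosen after that value was seen, decides nothing, since Rag1, Dntt, Arpp21 and Themis entered it by being detected on this array alone. Ptcra, detected on 3 others, lay 4.69 above their median. Of the Cd8b1 probes, that detected on 18 others lay 4.64 above, and those detected on all 41 others lay 4.495 and 0.46 above. These values, picked out after being seen, do not tell immature T cells of the lung from those of another tissue. Thymus carried over at dissection cannot be told apart from such cells: the thymic epithelial genes had a median of 0.593, under the bound of 1 set beforehand, but Prss16 and Psmb11 were detected on no array, which left Ccl25, detected here and on 29 others and 0.65 above the median. The thymus and lymph node list scored 0.011 on this array, inside the range of the others (-0.36 to 0.42). Only 7 of its 20 genes were tested, since the filter left out genes detected on few arrays, so this score decides nothing. Radiation stays open, since 1 such mouse among 29 irradiated and 0 among 13 controls gives a one-sided Fisher p of 0.690, the smallest a single case can give.

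On acute replicate 14, labelled female and without Xist, 2 of the 3 Y-linked genes tested, Eif2s3y at 5.91 and Kdm5d at 4.59, lay below the lowest male, at 8.11 and 5.34, while Uty at 5.47 lay inside the ranges of the males and of the other females, near the median of the latter (5.44, against 6.06 in males). This argues against a male sample with a wrong label, although Eif2s3y also lay above the highest of the other females, at 4.97. The mean of 4 X-linked genes that escape silencing was 8.56, above the male median of 8.52 set beforehand as the bound, inside the male range of 8.17 to 8.83 and just below the other females, at 8.56 to 9.28. Of these genes, picked out after their values were seen, Kdm6a at 10.02 and Eif2s3x at 9.93 lay at the male medians of 10.02 and 10.03 and below every other female (lowest 10.57 and 10.33), whereas Kdm5c at 5.81 and Ddx3x at 8.47 lay inside the range of both sexes. A single X chromosome therefore stays open and cannot be told apart from other losses of Xist signal, and no biological explanation given by the design was tested.

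The last 2 of 290 tested genes on the X chromosome, Arhgap6 (1.02 ± 0.098, adjusted p = 3.76e-10) and Hccs (0.81 ± 0.076, adjusted p = 2.17e-10), were higher in males, and were singled out after their values were seen. Both were higher in males on 7 of 7 slides, from 0.63 to 1.45 and from 0.62 to 0.98, so the difference was present within slides. For Arhgap6 all 22 males lay above the highest female, which fixed its direction on each slide in advance. Since both genes were picked on the same arrays, these counts are no separate test of slide as the source. The 5 nearest tested genes on the other side, Msl3, Prps2, Tlr7, Tlr8 and Tmsb4x, had a median of -0.19, within the limit of 0.2 to either side set beforehand, but ran from -0.81 for Tlr8 (adjusted p = 0.00150) and -0.66 for Tlr7 to 0.081 for Tmsb4x. The median therefore decides nothing, and an extra copy of that end of the chromosome in males cannot be told apart from other explanations. Chance neighbours stay open, since a share of 0.0672 of random orders put as many of the 5 X-linked genes called higher in males, each at its probe of highest mean, side by side, and sex itself, as a difference in regulation, was not tested.

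For the counts between groups, 100 splits of the samples were compared, the real one included. A real count of 0 is reached by every split, so nothing about chance was learned from the genes called in fractionated against control (real 0, highest other 0, 100 of 100 splits with as many), acute against control (0, 28, 100), fractionated against acute (0, 488, 100) and the F test (0, 0, 100). Chance could not be excluded for the lists called by camera, where 38 splits gave as many as the real 14 for fractionated against control (highest other 23), 85 as many as 4 for acute against control (23) and 84 as many as 8 for fractionated against acute (22). The median over the other splits was 12, 8 and 13 lists. Within slides, without fractionated replicate 13 and with slide as a block, 24 splits had as many probes at an unadjusted p under 0.05 as the real 1005 (highest other 4558), 43 as many as 696 (3028) and 63 as many as 506 (4838), so chance was not excluded. In the same splits 50 called as many lists as the real 10 for fractionated against control (highest other 21), 85 as many as 5 for acute against control (18) and 92 as many as 3 for fractionated against acute (20), so it was not excluded there. Some splits called 28 or 488 genes, and some lay several times above the real counts of lists or unadjusted probes. What in the samples gives rise to such counts was not tested.

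For sex, 3 of 100 splits of the labels within groups, the real one included, gave as many probes as the real 318. That share is small, but the highest other split called 732, so chance is not excluded by this test alone. What gave rise to such a count was not tested. Shuffled within slides, without fractionated replicate 13 and with slide as a block, 1 of 100 splits, the real one, gave as many as the real 868. The highest other count there was 0, which argues against chance for the count within slides. For the lists called by sex, 15 splits gave as many as 19 (highest other 24), and within slides 18 as many as 15 (highest other 22), so chance was not excluded. Nothing about chance was learned from the interactions with sex, where 100 of 100 splits give as many as the real 0 in fractionated (highest other 3) and in acute lungs (highest other 1), with 460 and 370 probes at an unadjusted p under 0.05 by limma.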
